A study of Homo sapiens with 16 samples.

How the data were processed

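The 16 libraries were QuantSeq 3' mRNA libraries, which read the 3' end of polyadenylated transcripts, from 4 human leukaemia cell lines that express Cas9 and carry a single guide RNA. Per the labels, total RNA was sequenced as single-end reads on a NextSeq 500, with STAR, HTSeq and the hg38 genome named as the tools. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Read length is given as either of 2 values without saying which library had which.

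The deposited files hold raw counts of reads per Ensembl gene, one file per library, with no normalisation. Each has 60107 gene entries and 92 spike-in entries, and the spike-in entries held 0 counts in all 16 libraries. The HTSeq summary lines for reads outside genes, ambiguous reads and reads aligned more than once were left out of the library totals. Gene counts summed to between 4078663 and 7531900 per library, with 15645 to 19890 genes having at least 1 count. Reads assigned to a gene made up 50.1% to 61.7% of the counted lines, reads aligned more than once 28.99% to 37.1%, and reads outside genes 4.01% to 14.7%. In a single library the upper limit that a count of 0 allows (3 counts) lay between 0.398 and 0.736 CPM. Reads carry no molecular identifier, so intervals and limits cover counting error only. Ratios with 1 to 3 counts in a group are given with a 95% exact interval for the ratio of 2 counts.

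Genes were named from a table of current symbols (40995 genes) and otherwise from GENCODE 29 (15536 genes), and 3576 genes stayed unnamed. Coordinates are those of GENCODE 29 on hg38. Because the strand setting is unknown, counts of overlapping and antisense genes are uncertain. Counts of close paralogues, such as histone and globin genes, depend on how reads aligned more than once were dropped.

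Each guide was compared with the non-targeting control guide of the same line, 2 libraries against 2. Counts were fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and edgeR's own filter on low counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-normalised counts scaled to library size (CPM), given as mean ± SD with n = 2 libraries per group, and the SE of a log2 fold change was derived from edgeR's F statistic. Differences of the MEF2D guide's effect between lines were tested as contrasts in one fit of the 12 libraries of MV4-11, THP1 and K562. Overlaps of called genes were tested with Fisher's exact test (two-sided). Correlations of fold changes between comparisons run across genes, which are not independent replicates; 6 such relations were computed.

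Before the data were examined, 21 gene lists with 555 members were fixed, and all members were found among the gene entries. They cover primary granule, CEBPE and secondary granule, monocyte and macrophage, HOXA and leukaemia stem cell, PU.1-activated, interferon-stimulated, p53 target, cell cycle, MYC target and ribosome biogenesis, erythroid, megakaryocyte, lymphoid, mast cell, MHC class II, immediate early and MEF2-linked, MEF2 family and class IIa HDAC, inflammatory, integrated stress response, mitochondrially encoded, cholesterol and fatty acid synthesis, and glycolysis and hypoxia genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over all 76 list tests. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone.

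The genes named were fixed by a rule before the data were examined. It names MEF2D, SPI1, CEBPE, CEBPA, IRF8, HOXA9, MEIS1 and MYC in every comparison. It adds the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM and both libraries of a group on one side, and up to 4 members of each list. Genes outside the rule are said to be chosen after their values were seen. Levels of sex-linked marker genes were not analysed here.

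The alternatives were RLE size factors, no filter and a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, one fit of all 16 libraries, the replicate number as a block, thinning to 4078663 counts, an absolute log2 fold change of at least 1, and leaving out each library in turn. Added after seeing the data were fits without mitochondrial and histone genes, with a trend of each library on GC content removed, and with the share of histone counts as a covariate. GC content was taken over the last 500 bases of the longest transcript of each gene. Where a group was left with 1 library, that library was assumed to vary like the others. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom 2.39 to 48.6), so no library was a copy of the other in its group; libraries of different groups were not compared.

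The fits were tested on simulated data with 2 libraries against 2 and the spread of each line. Of 67 genes changed 2-fold, 41 were recovered in MV4-11, 1 in THP1, 58 in K562 and 31 in MOLM13. Of 66 genes changed 4-fold, 54, 34, 62 and 60 were recovered. For differences between lines, 22, 21 and 30 of 66 differences of 4-fold were recovered, and at most 2 of 67 at 2-fold. A simulated list of 30 genes shifted by 0.5 on the log2 scale reached an unadjusted camera p under 0.05 in all 4 settings. With the preset correlation the highest camera p was 2.4e-11 (THP1). With an estimated correlation camera p lay between 0.0017 (K562) and 0.031 (MOLM13), and 0 of 100 unchanged lists per setting fell under 0.05. These p were not adjusted over the list tests. Among the real lists, a camera p of 0.016 with an estimated correlation (erythroid genes, K562) became 0.590 when adjusted. A miss after adjustment with an estimated correlation therefore cannot show that such a shift is absent. The simulated genes varied independently, so these runs did not test the preset correlation on lists whose members vary together. The estimated correlation was 0.712 for the interferon-stimulated genes in THP1, 0.598 for the inflammatory genes in MV4-11 and 0.0252 for the erythroid genes in K562. Where it was high, camera p at the preset correlation may be too low. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.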

Results

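The series measured gene expression after Cas9 editing with a guide against MEF2D or against PU.1 (gene SPI1), beside a non-targeting control guide. MEF2D is a transcription factor of the MEF2 family, and PU.1 is a transcription factor of myeloid and B cells. MOLM13, MV4-11 and THP1 are acute myeloid leukaemia lines that carry MLL fusions, and K562 is a BCR-ABL leukaemia line with erythroid features. The guide against MEF2D was used in MV4-11 and K562 (harvested at day 4 after infection) and in THP1 (day 10). The guide against PU.1 was used in MOLM13 (day 5). The titles of the THP1 libraries with the MEF2D guide and of the K562 controls carry an extra number, and whether it names another guide is not given in the sources used here. Each of the 8 groups held 2 libraries, and library totals ran from 4078663 gene counts (MOLM13 control 2) to 7531900 (MV4-11 MEF2D guide 2). The p-values below measure only the spread between these libraries, part of which may be technical.

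The first question was the level of the targeted transcripts. A 3' tag counts transcripts whether or not they carry an edit, so these values do not check editing. MEF2D (ENSG00000116604; chromosome 1, 156463727 to 156500828, minus strand) stood at 153 ± 36.6 CPM in MV4-11 controls and 137 ± 15.6 with its guide (log2 fold change -0.16, SE 0.19, n = 2 and 2, edgeR adjusted p = 0.999). In THP1 it stood at 239 ± 115 and 194 ± 5.93 (-0.31, SE 0.38). Both signs rested on control 1: without it the log2 fold change of MEF2D was 0.10 in MV4-11 and 0.29 in THP1. In K562 it stood at 8.88 ± 0.473 and 8.36 ± 0.277 (-0.08, SE 0.19), so its transcript was far lower in K562 than in either other line. Single libraries of K562 held 45, 62, 57 and 56 MEF2D counts. None of these passed the test. SPI1 (ENSG00000066336; chromosome 11, 47354860 to 47378576, minus strand) fell in MOLM13 from 54.1 ± 5.23 to 29.995 ± 11.2 CPM with the PU.1 guide (-0.86, SE 0.24, edgeR adjusted p = 0.0140). The 2 libraries with the guide held 171 counts (24.5 CPM before normalisation, 95% interval 20.95 to 28.4) and 212 counts (39.9, 34.7 to 45.7).

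The PU.1 guide in MOLM13 addressed which genes depend on PU.1 in this line. Among the falls were those of TYROBP, an adaptor of myeloid receptors, from 282 ± 92.0 to 39.6 ± 10.3 CPM (log2 fold change -2.84, SE 0.25), PTPRC (CD45) by -2.53 (SE 0.25), LILRB4 by -2.51 (SE 0.26) and the kinase BTK by -2.62 (SE 0.37). LYZ (lysozyme) fell from 1125 ± 44.4 to 226 ± 67.9 (-2.32, SE 0.23) and VCAN (versican) from 47.1 ± 4.98 to 2.85 ± 0.0173 (-4.04, SE 0.26). MEF2D itself fell from 206 ± 14.3 to 132 ± 17.7 (-0.64, SE 0.18, edgeR adjusted p = 0.0151). MYC rose from 59.3 ± 1.74 to 151 ± 15.2 (1.35, SE 0.18), and so did CEBPA (0.72, SE 0.19), IRF8 (0.61, SE 0.18) and MEIS1 (0.80, SE 0.20). HOXA9 was higher by 0.38 (SE 0.17) without passing (edgeR adjusted p = 0.108), and CEBPE stood at 4.92 ± 3.23 and 6.36 ± 3.15 (0.26, SE 0.45).

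**Figure D1:**
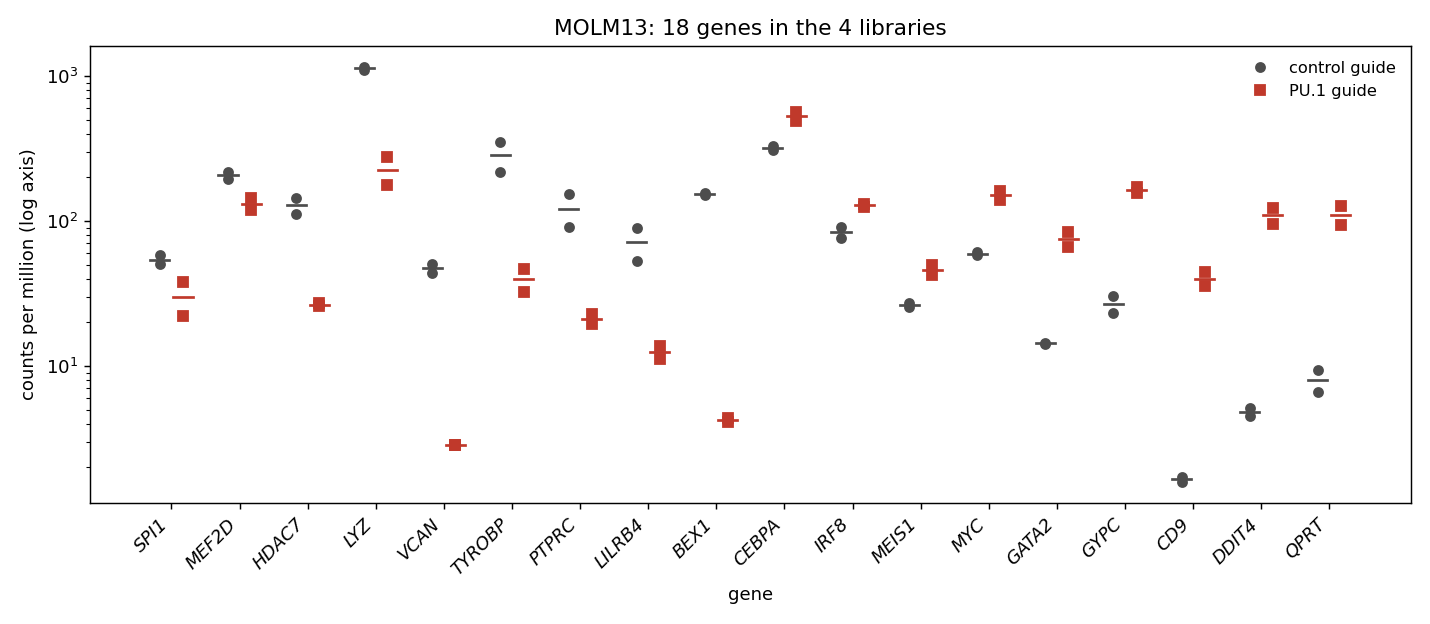
Normalised CPM (log axis) of 18 genes in the 4 MOLM13 libraries; grey circles are the 2 control libraries, red squares the 2 libraries with the PU.1 guide, and bars the group means. SPI1 fell from 54.1 to 29.995, while CD9 rose from 1.65 to 39.9 and BEX1 fell from 153 to 4.25.

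Among the largest rises in MOLM13 were CD9, a tetraspanin, from 1.65 ± 0.0927 to 39.9 ± 6.33 (log2 fold change 4.57, SE 0.32), and DDIT4, a stress-induced inhibitor of mTORC1, from 4.82 ± 0.465 to 109 ± 19.2 (4.48, SE 0.25). The enzyme QPRT rose by 3.75 (SE 0.25), RAB6B by 3.49 (SE 0.26), C3orf80 by 3.41 (SE 0.29), ZIC2 by 4.18 (SE 0.36), EBF3 by 5.78 (SE 0.42) and COL1A1 by 6.02 (SE 0.68). PTGDS was nearly absent from the controls, and its count ratio was 355 (95% interval 63.4 to 14036); that of IL32 was 101 (27.7 to 837). Among the largest falls were BEX1, from 153 ± 3.47 to 4.25 ± 0.192 (-5.16, SE 0.23), TASL, an adaptor of endosomal receptors (-5.29, SE 0.35), and the adhesion gene CADM1 (-4.19, SE 0.30). Other large falls had controls that differed widely from each other. H1-5 had 58.8 and 3.43 CPM in the 2 controls (-6.66, SE 1.13), H4C3 1319 and 291 (-4.40, SE 0.54), MT-ATP8 5312 and 1233 (-5.26, SE 0.60), PMM2 58.3 and 16.4 (-4.98, SE 0.56) and GTF2I 28.99 and 10.8 (-4.16, SE 0.49). H1-4 (-5.46, SE 0.90) and H2AC14 (-4.93, SE 0.82) behaved likewise, with 78.7 and 5.81, and 36.5 and 3.96.

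Over all 11158 genes tested in MOLM13, 32.4% were called (1471 up and 2144 down), which is the background for the list counts below. Counts near that share do not set a list apart. Of 37 tested PU.1-activated myeloid genes in MOLM13, 21 fell, 3 rose and 13 did not pass, and the same 21 and 3 counts held adjusted over the list alone. The median of the list was -0.69 (camera adjusted p = 3.7e-07; adjusted p = 0.590 with an estimated correlation). Of 18 monocyte and macrophage genes 10 fell, among them LILRB1 (-3.18, SE 0.49), 2 rose, among them LGALS3 (2.13, SE 0.31), and 6 did not pass (11 down and 2 up adjusted over the list alone). Its median was -1.10 (camera adjusted p = 8.2e-05; adjusted p = 0.590 with an estimated correlation). All 6 tested megakaryocyte genes changed: 4 rose, among them GATA2 (2.38, SE 0.22) and NFE2 (0.94, SE 0.20), and 2 fell, among them F13A1 (count ratio 12.9, 95% interval 4.00 to 66.6, control over guide), with the same counts adjusted over the list alone. Over the list the median was 0.81 (camera adjusted p = 0.00707; adjusted p = 0.590 with an estimated correlation). Of 15 mitochondrially encoded genes 12 fell and none rose, also adjusted over the list alone, with falls of MT-ND6 (-2.56, SE 0.29) and MT-ND5 (-2.47, SE 0.30). The list median was -1.30 (camera adjusted p = 2.0e-07; adjusted p = 0.590 with an estimated correlation). Of 32 MYC target and ribosome biogenesis genes 14 fell, among them GNL3 (-3.41, SE 0.48) and NOP56 (-1.59, SE 0.22), 2 rose and 16 did not pass (15 down and 2 up adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.0498; adjusted p = 0.590 with an estimated correlation).

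Of 24 integrated stress response genes 6 rose with the PU.1 guide, among them DDIT4, VEGFA (1.55, SE 0.24) and XBP1 (0.80, SE 0.19), and none fell (5 up adjusted over the list alone). The members' median was 0.33 (camera adjusted p = 0.0203; adjusted p = 0.590 with an estimated correlation). Of 21 immediate early and MEF2-linked genes 7 rose, among them KLF10 (1.87, SE 0.29) and KLF2 (2.46, SE 0.45), and 2 fell, HDAC9 (-1.40, SE 0.25) and DUSP6 (-1.23, SE 0.24), with 8 up and 2 down adjusted over the list alone. The list's median was 0.48 (camera adjusted p = 0.0493; adjusted p = 0.665 with an estimated correlation). The other lists did not pass camera in MOLM13. Within them 4 of 10 MEF2 family and class IIa HDAC genes fell and none rose (4 adjusted over the list alone; camera adjusted p = 0.0527): HDAC7, from 128 ± 22.4 to 26.4 ± 0.939 (-2.27, SE 0.20), HDAC9, MEF2C (-0.82, SE 0.19) and MEF2D. Primary granule genes split, with 6 of 16 falling, among them RNASE3 (-1.43, SE 0.19) and PRTN3 (-1.42, SE 0.22), and 4 rising, among them CST7 (1.47, SE 0.21) and AZU1 (1.26, SE 0.20), and the same counts adjusted over the list alone. Of 39 cell cycle genes 9 fell and 2 rose, over all genes and adjusted over the list alone, with falls of CENPE (-2.20, SE 0.20), TOP2A (-1.71, SE 0.23) and MKI67 (-1.45, SE 0.21). Of 17 interferon-stimulated genes 8 fell, among them XAF1 (-2.28, SE 0.21) and BST2 (-1.82, SE 0.21), and 1, IFITM3 (3.60, SE 0.57), rose (9 and 2 adjusted over the list alone). Of 11 erythroid genes 3 rose, among them GYPC (2.63, SE 0.20), and none fell (3 adjusted over the list alone).

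Of 21 HOXA, MEIS1 and leukaemia stem cell genes in MOLM13, 4 rose, among them RUNX2 (1.46, SE 0.24), and 6 fell, among them JMJD1C (-1.67, SE 0.21), with the same counts adjusted over the list alone. Of 24 p53 target genes 5 rose and 6 fell, among them XPC (-1.40, SE 0.22) and BAX (-2.63, SE 0.45; 5 and 8 adjusted over the list alone). Of 14 inflammatory genes 3 rose, among them TNFAIP2 (1.09, SE 0.18) and TNFAIP3 (1.07, SE 0.27), and NFKBIZ fell (-1.90, SE 0.53; 3 and 1 adjusted over the list alone). Of 25 glycolysis and hypoxia genes 7 rose, among them BNIP3 (1.52, SE 0.27), and none fell (3 adjusted over the list alone). Of 22 cholesterol and fatty acid genes 3 rose, among them ACACA (0.73, SE 0.19) and SREBF1 (0.79, SE 0.21), and none fell (2 adjusted over the list alone). Of 6 MHC class II genes CD74 alone fell (-0.78, SE 0.23), and of 5 lymphoid genes NCAM1 alone (-4.27, SE 0.43), in each case also adjusted over the list alone. Of 3 CEBPE and secondary granule genes CHI3L1 (2.24, SE 0.24) and S100P (1.57, SE 0.57) rose, also adjusted over the list alone; too few were tested for camera, as for the 2 mast cell genes, of which GATA2 rose.

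In all, 3615 of 11158 tested genes changed in MOLM13 by edgeR, 1471 up and 2144 down, 1892 of them by an absolute log2 fold change of at least 1. The share of histone counts moved with the guide: it was 0.187% and 0.0404% in the controls and 0.0131% and 0.00867% with the PU.1 guide, and mitochondrially encoded counts were 13.98% and 10.1% against 6.96% and 5.03%. The falls of the PU.1-activated and monocyte genes, the ribosome biogenesis falls and the rises above were measured in those same libraries. With the share of histone counts as a covariate in a fit of all 16 libraries, chosen after seeing the data, 812 genes were called, against 2843 in that fit without it. Without guide library 1 there were 2049 calls and without guide library 2 there were 2223. Leaving out control 2 ended the megakaryocyte call (camera adjusted p = 0.0670), and leaving out control 1 ended those of the immediate early and MEF2-linked genes (0.0701) and of the integrated stress response genes (0.0555). Without guide library 1 the immediate early and MEF2-linked genes (0.138) and ribosome biogenesis genes (0.0509) missed the threshold, as did ribosome biogenesis (0.0505) and stress response genes (0.0505) without guide library 2. One fit of all 16 libraries ended the calls of the megakaryocyte (0.437), ribosome biogenesis (0.128), stress response (0.0809) and immediate early and MEF2-linked genes (0.0641).

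**Figure D2:**
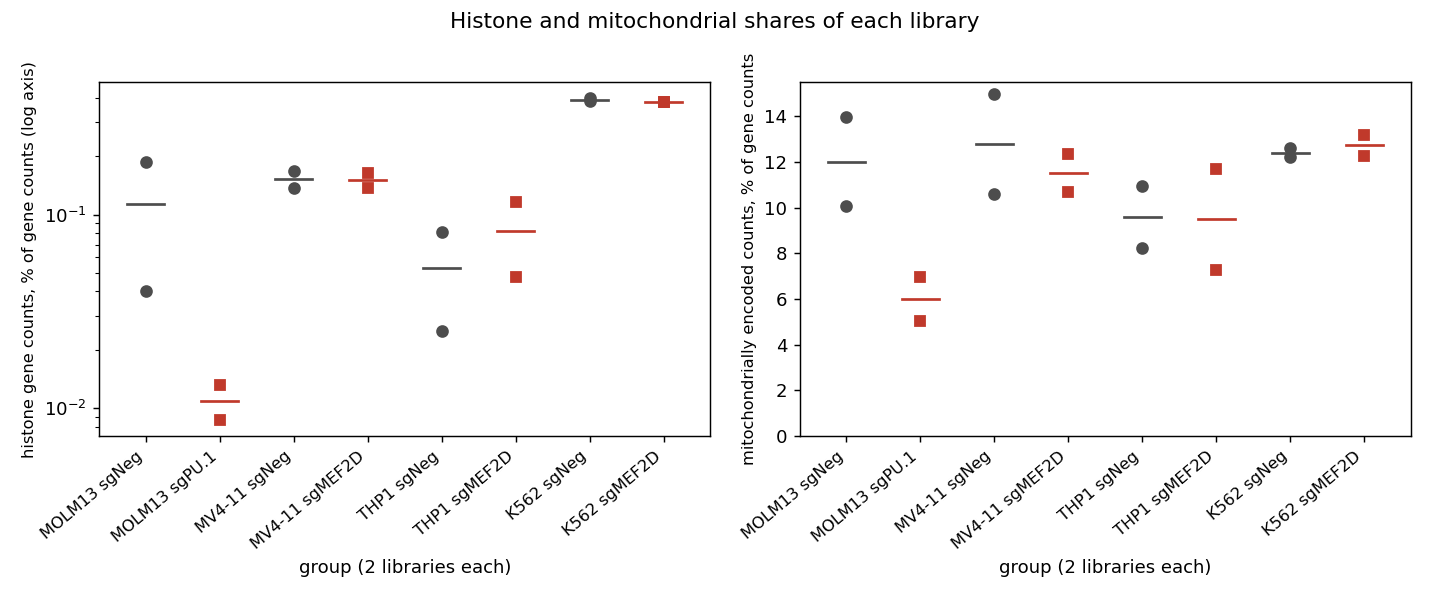
Share of gene counts from histone genes (left, log axis, in %) and from mitochondrially encoded genes (right, in %) in each library; grey circles are control libraries, red squares libraries with a targeting guide, and bars the means of the 2 libraries. The MOLM13 libraries with the PU.1 guide have the lowest values in both panels, 0.00867% to 0.0131% and 5.03% to 6.96%.

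The MEF2D guide in MV4-11 asked which genes depend on MEF2D in this line. No gene passed in the edgeR fit of 2 against 2 libraries without a replicate block, against 184 with one. The lowest p-values belonged to genes that were lower with the guide. IRF8, a transcription factor of the monocyte and dendritic lineages (chromosome 16, 85898803 to 85922609, plus strand), stood at 222 ± 56.4 CPM in controls and 99.0 ± 1.70 with the guide (log2 fold change -1.16, SE 0.19, edgeR adjusted p = 0.104). HDAC9, a class IIa deacetylase that binds MEF2 factors, stood at 12.4 ± 2.31 and 2.03 ± 0.375 (-2.64, SE 0.38, edgeR adjusted p = 0.104). CD53, a leukocyte tetraspanin, stood at 123 ± 6.01 and 62.7 ± 1.89 (-0.97, SE 0.16, edgeR adjusted p = 0.104). By DESeq2 these 3 genes passed, IRF8 with an adjusted p of 0.00127, HDAC9 with 0.00369 and CD53 with 0.00497.

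The inflammatory cytokine and NF-kB genes were shifted down in MV4-11: all 16 tested were lower, none passed over all genes and 5 fell adjusted over the list alone. Their median was -0.57 (camera adjusted p = 1.4e-10; adjusted p = 0.590 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB signalling, was at -1.67 (SE 0.37), PLAUR at -0.62 (SE 0.17), IL1B at -2.37 (SE 0.73) and CCL4 at -2.05 (SE 0.66). The PU.1-activated myeloid genes were shifted down, with 26 of 37 lower, none passing over all genes and 6 falling adjusted over the list alone. The members' median was -0.13 (camera adjusted p = 0.000273; adjusted p = 0.590 with an estimated correlation). LST1 was at -0.66 (SE 0.16) and LILRB4 at -0.78 (SE 0.21). The primary granule and promyelocyte genes were shifted up, with 14 of 15 higher, none passing over all genes and 1 rising adjusted over the list alone. The median of the list was 0.27 (camera adjusted p = 2.2e-06; adjusted p = 0.590 with an estimated correlation). Among them CTSG (cathepsin G) was at 0.86 (SE 0.20), RNASE2 at 0.43 (SE 0.18), ELANE at 0.41 (SE 0.20) and MPO at 0.59 (SE 0.32). The cholesterol and fatty acid synthesis genes were shifted up, with 17 of 22 higher and none passing, also adjusted over the list alone. Over the list the median was 0.26 (camera adjusted p = 8.2e-05; adjusted p = 0.661 with an estimated correlation). FASN was at 0.49 (SE 0.14) and ACACA at 0.62 (SE 0.21).

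Other lists did not pass in MV4-11. FLT3 was at -0.67 (SE 0.16) and SOX4 at -0.51 (SE 0.16) among the HOXA, MEIS1 and leukaemia stem cell genes (median -0.06, camera adjusted p = 0.0701), and CD74 at -0.71 (SE 0.21) among the MHC class II genes (median -0.32, 7 of 9 lower, camera adjusted p = 0.0701). HOXA9 was at -0.18 (SE 0.17), MEIS1 at -0.01 (SE 0.18), MYC at -0.35 (SE 0.20), CEBPA at 0.26 (SE 0.14) and SPI1 at 0.01 (SE 0.19). CEBPE was not tested, since the 4 libraries held only 3, 7, 4 and 6 counts. Of the MEF2 family and class IIa HDAC genes (10 tested, median -0.03, camera adjusted p = 0.129) only HDAC9 fell adjusted over the list alone. Median and mean differed in sign for the glycolysis and hypoxia genes (0.02 and -0.04, camera adjusted p = 0.981). By edgeR 0 of 11539 genes passed, with 547 at an unadjusted p under 0.05 (577 by chance) and a lowest adjusted p of 0.104; DESeq2 called 14, 1 up and 13 down, and edgeR without a filter called 87. Leaving out 1 library gave 40 calls (without control 1), 27 (control 2), 35 (guide library 1) and 32 (guide library 2). Without control 1 the cholesterol call (adjusted p = 0.830) and the inflammatory call (0.0998) ended, and without guide library 2 the primary granule call did (0.0561).

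The MEF2D guide in THP1 asked the same question at day 10, and no gene passed in the edgeR fit of 2 against 2 libraries. The interferon-stimulated genes were shifted down: 36 of 38 were lower, and none passed over all genes or adjusted over the list alone. The list median was -0.73 (camera adjusted p = 1.8e-17; adjusted p = 0.590 with an estimated correlation). MX1 stood at 274 ± 65.4 CPM in controls and 115 ± 72.3 with the guide (log2 fold change -1.25, SE 0.45, edgeR adjusted p = 1.00), OAS2 was at -1.01 (SE 0.41), IFIH1 at -0.99 (SE 0.39) and SAMD9L at -0.89 (SE 0.41). The monocyte and macrophage genes were shifted up, with 14 of 20 higher, none passing over all genes and 3 rising adjusted over the list alone. Its median was 0.34 (camera adjusted p = 0.000257; adjusted p = 0.590 with an estimated correlation). The monocyte receptor CD14 stood at 9.60 ± 0.444 and 31.3 ± 3.68 (1.70, SE 0.33, edgeR adjusted p = 0.729), and APOE was at 1.40 (SE 0.39), while FCGR1A was at -0.96 (SE 0.31).

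The inflammatory cytokine and NF-kB genes were shifted up in THP1, with 17 of 21 higher, none passing over all genes and 1 rising adjusted over the list alone. Their median was 0.32 (camera adjusted p = 8.2e-05; adjusted p = 0.590 with an estimated correlation). The chemokine CXCL8 was at 2.88 (SE 0.60), TNF at 1.58 (SE 0.60) and CXCL1 at 1.78 (SE 0.78). The immediate early and MEF2-linked genes were shifted up, with 14 of 20 higher, none passing over all genes and 2 rising adjusted over the list alone. The members' median was 0.62 (camera adjusted p = 8.2e-05; adjusted p = 0.590 with an estimated correlation). EGR1 was at 1.38 (SE 0.32), JUN at 1.16 (SE 0.30) and DUSP1 at 2.48 (SE 0.81), and HDAC9 at -0.98 (SE 0.33). The HOXA, MEIS1 and leukaemia stem cell genes were shifted down, with 15 of 21 lower, none passing over all genes and 1 falling adjusted over the list alone. The median of the list was -0.19 (camera adjusted p = 0.0207; adjusted p = 0.612 with an estimated correlation). BCL2, an inhibitor of apoptosis, was at -1.46 (SE 0.34), LMO2 at -0.71 (SE 0.43) and HOXA9 at -0.08 (SE 0.31). LILRB4 stood at 69.0 ± 2.77 and 23.3 ± 0.550 (-1.56, SE 0.31, edgeR adjusted p = 0.729). IRF8 was at -0.59 (SE 0.34), CEBPE at 1.11 (SE 0.44), SPI1 at -0.26 (SE 0.33), CEBPA at 0.22 (SE 0.34) and MYC at -0.36 (SE 0.32). MEIS1 had 4, 0, 0 and 1 counts in the libraries and was not tested.

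The signs of median and mean differed in THP1 for the p53 target (-0.11 and 0.02), lymphoid (0.19 and -0.12) and megakaryocyte genes (0.06 and -0.05), none of which passed. The MEF2 family and class IIa HDAC genes did not pass either (median -0.11, camera adjusted p = 0.142). By edgeR 0 of 12650 genes passed in THP1, with 332 at an unadjusted p under 0.05 (632.5 by chance) and a lowest adjusted p of 0.114. DESeq2 called 6, 1 up and 5 down. They included CXCL8 (adjusted p = 0.0334) and LILRB4 (0.0444), and AXL, a receptor kinase chosen here after its values were seen, at 54.1 ± 18.8 and 6.42 ± 0.563 CPM (-3.07, SE 0.39; DESeq2 adjusted p = 7.6e-08, edgeR adjusted p = 0.114). The THP1 controls differed from each other more than any other pair (chi-square per degree of freedom 48.6), with PHGDH at 420 and 77.3, PSAT1 at 663 and 89.2, and ASNS at 115 and 22.8 CPM; these are serine and asparagine synthesis genes of the integrated stress response list, which did not pass (median -0.54, camera adjusted p = 0.0701). Leaving out control 2 gave 159 calls (89 up, 70 down), control 1 gave 2 (0 up), guide library 1 gave 5 (3 up) and guide library 2 gave 35 (9 up), so the balance of rises and falls turned with the library left out. Without control 1 the calls of the monocyte (adjusted p = 0.814), HOXA (0.652) and immediate early and MEF2-linked genes (0.286) ended. Without guide library 1 those of the interferon-stimulated (0.0586), HOXA (0.0502) and immediate early and MEF2-linked genes (0.0502) ended, and without guide library 2 that of the HOXA genes (0.203). One fit of all 16 libraries ended that of the monocyte genes (0.0960).

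In K562 the MEF2D guide was used in a line with little MEF2D transcript, and 55 of 11640 genes changed by edgeR, 42 up and 13 down, with small fold changes (median absolute log2 fold change 0.46, and 2 of at least 1). Erythroid genes rose: 7 of 30 passed over all genes and 14 adjusted over the list alone, all upward, and 25 were higher. Over the list the median was 0.28 (camera adjusted p = 1.8e-17; adjusted p = 0.590 with an estimated correlation). The embryonic globin HBE1 rose from 7076 ± 262 to 8992 ± 15.4 CPM (log2 fold change 0.35, SE 0.05, edgeR adjusted p = 0.00293), and HBZ by 0.54 (SE 0.07). The glycophorin GYPB rose by 0.49 (SE 0.06), and the mitochondrial iron importer SLC25A37 by 0.46 (SE 0.07). The largest rises at a mean of at least 10 CPM were PRRC2A, from 16.6 ± 0.614 to 37.2 ± 4.00 (1.17, SE 0.13, edgeR adjusted p = 0.000175), SGTA (0.96, SE 0.12), RNY3 (0.87, SE 0.18), MCAM (0.84, SE 0.13), FAM178B (0.84, SE 0.13), MRPL28 (0.82, SE 0.15), DTX2 (0.80, SE 0.16), VTRNA1-3 (0.74, SE 0.13), SCARNA9 (0.69, SE 0.12) and E4F1 (0.69, SE 0.13).

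The largest falls in K562 were the growth factor IGF1, from 229 ± 2.12 to 160.1 ± 4.09 CPM (-0.52, SE 0.06), the serine synthesis enzyme PHGDH (-0.51, SE 0.11), ITPKA (-0.44, SE 0.10), FCGR2A (-0.43, SE 0.08), TSC22D2 (-0.41, SE 0.09), NFE4 (-0.41, SE 0.09), GLRX2 (-0.39, SE 0.08), CSRNP1 (-0.38, SE 0.08), CD69 (-0.36, SE 0.08) and EGR1 (-0.35, SE 0.06). Of 24 integrated stress response genes PHGDH and PSAT1 (-0.33, SE 0.07) fell, also adjusted over the list alone, and of 21 p53 target genes GDF15 rose (0.45, SE 0.06), also adjusted over the list alone. No list other than the erythroid genes passed camera in K562. Median and mean differed in sign for the lymphoid (-0.03 and 0.11), immediate early and MEF2-linked (-0.13 and 0.01) and mitochondrially encoded genes (-0.01 and 0.02). SPI1 was at 0.48 (SE 0.18), MYC at 0.16 (SE 0.10) and MEIS1 at -0.23 (SE 0.24) without passing. CEBPE and CEBPA had at most 5 counts in a library, and IRF8 and HOXA9 had 0, which allows up to 0.412 to 0.612 CPM.

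GC content moved with these genes: over the last 500 bases of the transcript its median was 55.5% in the risen genes, 36.8% in the fallen genes, 50.8% in the erythroid list and 42% in all tested genes. With a GC trend removed from each library, chosen after seeing the data, 22 genes were called, of which 21 were among the 55. DESeq2 called 13 genes, all of them among the 55, and one fit of all 16 libraries called 0. Leaving out control 1 gave 448 calls, control 2 gave 96 and guide library 2 gave 32. The erythroid list passed without any single library, with a highest camera adjusted p of 6.0e-12.

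**Figure D3:**
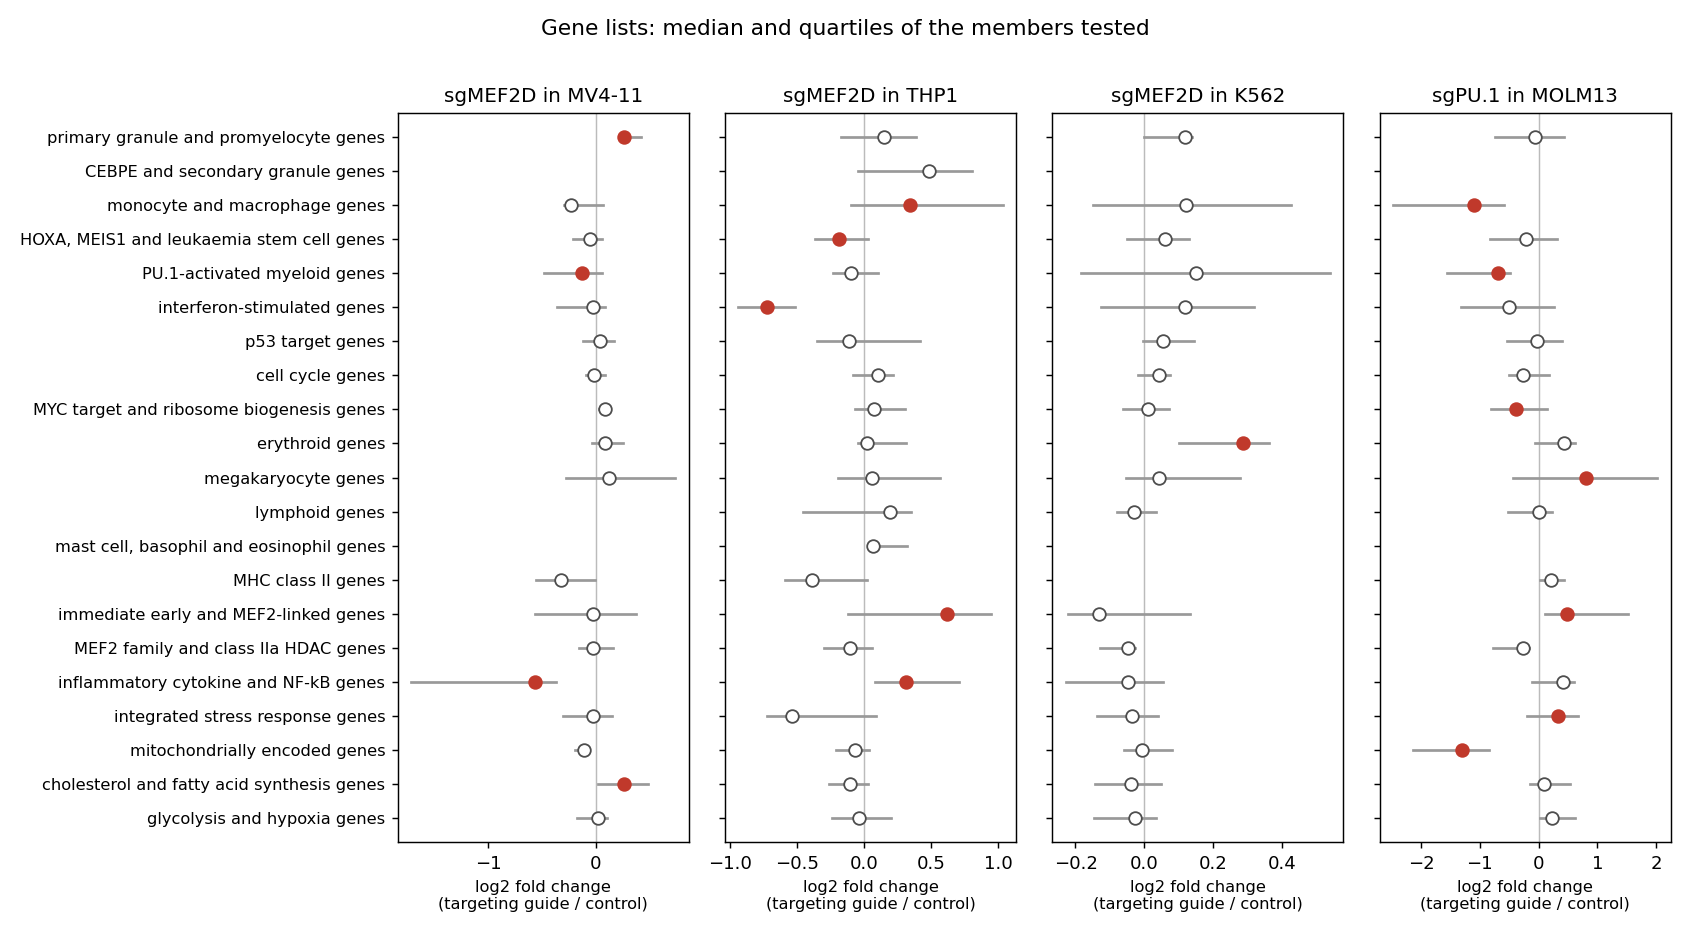
Median log2 fold change (targeting guide over control, circles) and quartiles (bars) of the tested members of the 21 gene lists in the 4 comparisons, with different x scales; filled circles passed camera at the preset correlation, and lists with under 5 tested members are left blank. The inflammatory genes lie at -0.57 in MV4-11 and 0.32 in THP1, the interferon-stimulated genes at -0.73 in THP1, the erythroid genes at 0.28 in K562, and the PU.1-activated genes at -0.69 in MOLM13.

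The remaining comparisons asked whether targeting MEF2D acted alike in the 3 lines. Single genes gave no answer: the difference tests in edgeR called 0 of 14718 genes between MV4-11 and K562 (274 at an unadjusted p under 0.05), 0 between THP1 and K562 (460) and 0 between THP1 and MV4-11 (455). Each of these counts lay below the 735.9 genes expected by chance. DESeq2 called 0, 3 and 2. Across 10868 genes the log2 fold changes of MV4-11 and THP1 correlated with Pearson's r of 0.248 and Spearman's rho of 0.262 (jackknife SE over libraries 0.0887), and r was 0.102 without THP1 control 2 and 0.130 without THP1 guide library 1. The other 5 correlations lay between -0.02 and 0.08. Leaving out 1 library moved that of THP1 and MOLM13 between -0.0806 (without THP1 control 2) and 0.185 (THP1 control 1). That of MV4-11 and MOLM13 moved between -0.0739 (without MV4-11 control 2) and 0.0464 (MV4-11 control 1). HDAC9 and LILRB4 were lower with the guide in both lines, as given above. CDC42EP3, the only gene that DESeq2 called in both and chosen after its values were seen, stood at 140 ± 2.78 and 77.7 ± 1.56 CPM in MV4-11 (-0.85, SE 0.16; DESeq2 adjusted p = 0.0187, edgeR adjusted p = 0.186) and at 41.9 ± 7.13 and 12.2 ± 1.22 in THP1 (-1.78, SE 0.33; DESeq2 adjusted p = 0.0400, edgeR adjusted p = 0.729). Of 28 genes that rose in K562 and were tested in MOLM13, 10 rose there too (3.59 by chance, Fisher's exact p = 0.00170), and of 10 that fell 1 fell there (1.87 by chance, exact p = 0.700), while 10 genes changed in opposite directions. The 11 genes shared in one direction were 2 by DESeq2, 0 with all 16 libraries in one fit, 29 without a filter and 17 with thinned libraries. They were 80 without K562 control 1, 18 without K562 control 2, 7 without K562 guide library 2 and 3 without MOLM13 guide library 1, so the overlap depends on these settings. With 0 genes called by edgeR without the replicate block in MV4-11 and in THP1, no other pair of comparisons could overlap.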

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

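Of the tests in this part, the difference tests of gene lists between lines and the tests of histone, S phase and mitochondrially encoded genes, as well as the GC-matched random lists, were chosen only after the results were seen. With camera at the preset correlation, 9 of 63 list differences of the MEF2D guide's effect between lines passed, and 0 with an estimated correlation. The inflammatory genes differed between THP1 and MV4-11 (camera adjusted p = 2.3e-12, 25 genes, median difference 0.79), with 21 genes higher in THP1 and no library whose omission ended the call (highest adjusted p = 0.000122). The inflammatory genes also differed between MV4-11 and K562 (0.00558, median -0.29) and between THP1 and K562 (0.0139, median 0.52). The interferon-stimulated genes differed between THP1 and K562 (6.4e-05, median -0.82) and between THP1 and MV4-11 (0.000100, median -0.58). The immediate early and MEF2-linked genes differed between THP1 and MV4-11 (6.4e-05, median 0.45) and between THP1 and K562 (0.000100, median 0.84). The cholesterol and fatty acid genes differed between MV4-11 and K562 (0.00298, median 0.33) and between THP1 and MV4-11 (0.0333, median -0.23). Many members passed the filter on low counts in 1 of the lines alone: of 38 interferon-stimulated genes 14 were tested in K562 and 18 in MV4-11, and of 25 inflammatory genes 21 in THP1, 16 in MV4-11 and 14 in K562. Over the members tested in both lines, a restriction also chosen after the results were seen, the 9 differences kept their direction. The interferon medians were -0.75 (n = 14 genes, SD 0.264, camera p = 2.3e-08) against K562 and -0.58 (n = 18 genes, SD 0.365, camera p = 7.8e-08) against MV4-11. The inflammatory medians were 0.71 for THP1 and MV4-11 (n = 15 genes, SD 1.06, camera p = 2.3e-11), -0.42 for MV4-11 and K562 (n = 10 genes, SD 0.838, camera p = 0.00111) and 0.35 for THP1 and K562 (n = 11 genes, SD 0.995, camera p = 0.00202). With an estimated correlation these p were 0.0748, 0.126, 0.0185, 0.144 and 0.193 in that order (n = 10 genes or more).

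The other 8 differences were lost without single libraries. Both interferon differences ended without THP1 guide library 1 (adjusted p = 0.542 against K562 and 0.906 against MV4-11), and both immediate early and MEF2-linked differences without THP1 control 1 (0.154 against MV4-11, 0.176 against K562). The cholesterol difference of MV4-11 and K562 ended without MV4-11 control 1 (0.746) or guide library 2 (0.129). That of THP1 and MV4-11 ended without either of those libraries (0.811, 0.313), THP1 control 1 (0.469) or THP1 guide library 1 (0.709). The inflammatory difference of MV4-11 and K562 ended without MV4-11 control 1 (0.811), MV4-11 guide library 1 (0.123), K562 control 2 (0.146) or K562 guide library 1 (0.147). That of THP1 and K562 ended without THP1 control 1 (0.278), THP1 guide library 2 (0.134), K562 control 1 (0.172) or K562 guide library 2 (0.0852).

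For the inflammatory genes in THP1 and MV4-11, a difference between libraries that the share of histone counts follows was tested as a technical explanation. With that share as a covariate the median difference was 0.796 (SD 1.98, n = 27 genes, camera p = 1.1e-10), against 0.801 without it. Under one slope shared by all 4 lines, this argues against such a library difference as the cause of the THP1 part. In MV4-11 the share hardly differed between controls (0.138% and 0.169%) and guide libraries (0.137% and 0.164%). The covariate could therefore hardly change the MV4-11 part, and library differences that the share does not follow were not tested. The lines also differ in their day of harvest (10 against 4), which the design does not separate from the line, and the titles leave open whether they share one MEF2D guide. A difference in response to the MEF2D guide may remain as a hypothesis, with the day, the guide and other library differences as untested alternatives.

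In MOLM13, 8 of 14 histone genes fell with the PU.1 guide and 1 rose, along with falls of the mitochondrially encoded and PU.1-activated genes. The 8 fallen histone genes had a median log2 fold change of -4.54. The fallen histone genes also part the controls of THP1 by a median of 2.031 (log2) and those of MOLM13 itself by 2.50, but those of MV4-11 by 0.262 and of K562 by 0.189. A difference in RNA or library quality apart from the guide may explain the histone falls in part or as a whole. Fewer cells in S phase are argued against by the S phase genes (median 0.0197, SD 0.567, 14 genes). Over the whole cell cycle list 26 of 39 genes were lower, with 9 called down and 2 up (median -0.26, camera adjusted p = 0.154). A change in other parts of the cell cycle is therefore not excluded. With the share of histone counts as a covariate the PU.1-activated genes kept a median of -0.956 (SD 1.12, n = 39 genes, camera p = 4.3e-08; -0.61 without it), and the mitochondrially encoded genes -1.03 (SD 0.863, n = 15 genes, camera p = 3.1e-05; -1.26 without it). With an estimated correlation these p were 0.00464 (n = 39 genes) and 0.182 (n = 15 genes; 0.0707 without the covariate). Both lists thus kept their falls under one slope shared by all 4 lines, for the mitochondrially encoded genes at the preset correlation only. In MOLM13 the histone share was lower in both guide libraries (0.0131% and 0.00867%) than in either control (0.187% and 0.0404%). The fit therefore cannot decide whether that library difference caused these falls in MOLM13. The monocyte genes went from -0.75 (SD 1.87, n = 23 genes, camera p = 0.00353) to -0.55 (SD 2.29, camera p = 0.538). Their call ended with the covariate, the cause was not tested, and for them too the explanation stays open.

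In K562 the erythroid list passed camera at the preset correlation but not with an estimated one (adjusted p = 0.590), and 7 of its 30 tested genes were called, all upward. Its genes are richer in GC than other genes, and log2 fold changes followed GC content (Spearman's rho 0.180; 0.159 in MV4-11, 0.168 in THP1 and 0.0711 in MOLM13). With the trend on GC content removed, the erythroid median was 0.208 (SD 0.360) against 0.28 before. It kept a fraction of 0.729 of its size, between the bounds set beforehand, so a GC content bias as a part of the shift cannot be told apart from an effect of the guide. Of 10000 random lists matched on GC content, 0 reached the erythroid median (highest 0.211), which argues against GC content as the whole cause. An effect of the MEF2D guide may remain as a hypothesis for the rest, although MEF2D had 45 to 62 counts per library in this line. Other differences between control and guide libraries were not tested, and the control titles carry an extra number of unknown meaning. Lists of random genes cannot exclude a shift that erythroid genes share for a reason other than the guide.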

How the results depend on the processing

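The fits without mitochondrial and histone genes, with a GC trend removed and with the histone share as a covariate were chosen after seeing the data. In the fits that leave out 1 library, the lone sample is assumed to vary like the other groups. No called gene that the text names changed direction under the alternatives fixed beforehand. No list past the threshold did so either, though lists were not run with DESeq2 or thinned libraries. Direction was not checked for the other called genes or in the fits chosen after seeing the data. Counts of changed genes with RLE size factors or a stricter filter stayed within 1.5 times (0 in MV4-11 and in THP1, 52 and 44 in K562, 3556 and 3284 in MOLM13, against 0, 0, 55 and 3615), and those without mitochondrial and histone genes were 0, 0, 61 and 3681. Without a filter there were 87 in MV4-11, 40 in THP1 and 166 in K562; with DESeq2 14, 6 and 13; with all 16 libraries in one fit 2, 8 and 0; with the histone share as a covariate 3, 21, 0 and, in MOLM13, 812. With the replicate block MV4-11 had 184 (45 up and 139 down, with IRF8, HDAC9 and CD53 among the falls). The replicate numbers are not known to name shared batches. Across genes, the difference between the replicates of the control group correlated with that of the guide group. This correlation was 0.307 in MV4-11, -0.227 in THP1, 0.0363 in K562 and 0.172 in MOLM13. In MV4-11 the libraries also paired by number in gene counts (4273688 and 4221277 for replicate 1, 7431030 and 7531900 for replicate 2). Their histone shares did so too (0.138% and 0.137%, against 0.169% and 0.164%). In MOLM13 replicate 2 had the lower histone share in both groups (0.0404% against 0.187%, and 0.00867% against 0.0131%). THP1 histone shares did not pair (0.025% and 0.116%, against 0.0815% and 0.0477%). A factor shared by libraries of one number stays open in MV4-11 and MOLM13. K562 had 129 when thinned and 22 with the GC trend removed, and an absolute log2 fold change of at least 1 left 2 in K562 and 1892 in MOLM13. Leaving out 1 library gave 27 to 40 in MV4-11, 2 to 159 in THP1 (89 up and 70 down at most), 32 to 448 in K562 and 2049 to 4621 in MOLM13. Differences between lines numbered 8 (MV4-11 and K562), 14 (THP1 and K562) and 21 (THP1 and MV4-11) without a filter, 3 and 2 for the last pairs with DESeq2, and 0 to 2 and 0 to 14 for them on leaving out 1 library. The correlation of MV4-11 and THP1 (0.248) was 0.0804 without a filter, 0.113 with all 16 libraries and 0.102 to 0.240 on leaving out 1; that of MV4-11 and K562 was -0.0456 to 0.0569 and that of THP1 and K562 -0.0377 to 0.0336. Shared genes of one direction were, without a filter, 5 (MV4-11 and THP1), 20 (MV4-11 and MOLM13), 2 (THP1 and K562), 12 (THP1 and MOLM13) and 29 (K562 and MOLM13); with DESeq2 1, 4, 0, 2 and 2; with all 16 libraries 1 for MV4-11 and MOLM13, 3 for THP1 and MOLM13 and 0 for K562 and MOLM13. The block gave 51 for MV4-11 and MOLM13, and thinning 17 for K562 and MOLM13. Leaving out 1 library gave 0 to 19 (MV4-11 and MOLM13), 0 to 4 (THP1 and K562), 0 to 23 (THP1 and MOLM13) and 3 to 80 (K562 and MOLM13). Lists past the threshold fell to 0 in all 4 comparisons with an estimated correlation and with fry. With the replicate block they were 8 in MV4-11 and 4 in K562; in K562 2 with RLE size factors, 4 without a filter and 2 with a stricter filter; in MOLM13 3 with all 16 libraries. Leaving out 1 library gave 4 to 10 in THP1 and 2 to 3 in K562. For these shifts the cause was not tested.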

Other observations

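The test of the hypothesis below was chosen only after the results were seen. The genes that fell with the PU.1 guide in MOLM13 were asked whether they also fall with the MEF2D guide, since a shared program may link both factors. In MV4-11 51.4% of such genes were lower (n = 2038 genes, camera p = 0.844), and in THP1 61.3% (n = 2079 genes, camera p = 0.0144; p = 0.562 with an estimated correlation). In K562 49.7% were lower (n = 1835 genes, camera p = 0.803). In MV4-11 the set as a whole thus showed no shift (median -0.01, SD 0.297), much as in K562. In THP1 it lay slightly lower (median -0.08, SD 0.38), at the preset correlation only. These values do not bear out a general fall in MV4-11, and the hypothesis stays open for THP1 and for single genes. Among the genes named above, HDAC9 (-2.64, -0.98 and -1.40) and LILRB4 (-0.78, -1.56 and -2.51) were lower in MV4-11, THP1 and MOLM13. They were picked here after their values were seen. IRF8 and MYC were lower in MV4-11 and THP1 but rose in MOLM13, and TNFAIP3 was lower in MV4-11 but rose in MOLM13. In the edgeR fits of 2 against 2 libraries without a replicate block, HDAC9 and LILRB4 passed in MOLM13 alone. With the block HDAC9 also passed in MV4-11, and DESeq2 called HDAC9 in MV4-11 and LILRB4 in THP1. With all 16 libraries in one fit HDAC9 passed in MV4-11 (edgeR adjusted p = 0.00997) and LILRB4 in THP1 (edgeR adjusted p = 0.0467).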
